A study of Gallus gallus with 20 samples.

How the data were processed

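Total RNA of liver was prepared, per the labels, with an RNeasy mini kit and made into libraries with the TruSeq Stranded Total RNA kit with Ribo-Zero Globin, from chickens of the breeds Ogye and Cornish aged 5 or 10 weeks. Each of the 4 groups has 5 libraries, and the labels name them by breed, age and a number from 1 to 5. The labels give neither the sex of the birds nor whether the libraries of a group came from different birds.

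The deposited table holds raw counts for 20 libraries, which the authors made, per the submitters' processing notes, with FastQC and MultiQC for read quality, STAR for alignment to the build GRCg7b and featureCounts for counting. Versions, parameters, the strand setting of the counting and the assembler of the unnamed transcripts are not given in the sources used here. The table has 54062 entries, of which 13956 are named by a gene symbol, 40097 carry names of the form that StringTie gives to assembled transcripts and 9 have no gene name. Of the named entries 12769 matched a symbol of the RefSeq table for the same build, which gave positions, biotypes and gene length as the span on the chromosome. Assembled entries held between 30.4% and 37% of the counts of a library and entries without a gene name between 0.013% and 0.059%. All comparisons use the named genes, a choice made once the kinds of entries were known and before any gene was tested, since many assembled entries repeat the counts of named genes. Fits to all entries are given beside them.

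Totals ran from 14865637 to 31848768 counts per library, and from 9625549 to 21106844 on named genes. A count of 0 was read as allowing up to 3 counts, a floor that covers counting error only, as reads without molecular identifiers are not independent molecules. No 2 libraries had identical columns, and the highest Spearman correlation between 2 libraries was 0.986.

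Genes were kept by the filterByExpr function of edgeR with the 4 groups, which left 10697. Scaling used the TMM factors of edgeR, and CPM are counts per 1e+06 scaled counts of named genes. A single model with a mean for each group was fitted to the 20 libraries with edgeR 4.0.16 by robust quasi-likelihood in R 4.3.3. From it came 5 contrasts, namely Cornish minus Ogye at 5 weeks, Cornish minus Ogye at 10 weeks, 10 minus 5 weeks in Ogye, 10 minus 5 weeks in Cornish, and the interaction as the breed effect at 10 weeks minus that at 5 weeks. All tests were 2-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and a sub-count takes those with an absolute log2 fold change of at least 1. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Principal components were taken from log2 CPM.

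Gene lists, 30 in number, cover hormone axes, lipid, sugar, amino acid and bile acid metabolism, detoxification, energy and protein production, stress and immune responses, pigmentation, the clock, and markers of the other cell types that a liver sample can hold. They were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation between genes estimated from the data. Genes of each list were also adjusted over the list alone. Genes within 500 kb of EDN3 were counted separately. Long non-coding RNA were compared with protein-coding genes by Fisher's exact test.

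Named genes follow a fixed rule. For each contrast it takes the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 1 CPM in the higher group, with no overlap between the libraries compared and with a symbol that is not a locus identifier. For the interaction the overlap was not asked for. It adds up to 4 members with the lowest adjusted p of each list described, and IGF1, IGF2, GHR, IGFBP2, EDN3, FASN, CYP7A1 and THRSP in every contrast. ALB, HINTW, STX16, ACOT8, CTSA, ZSWIM1, POLD4 without the 3 libraries and TF per library are given outside this rule and were chosen after their values were seen. A few genes that the rule takes are not reported here, nor screened for single outlying libraries.

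Grouping, contrasts, tests, gene lists, the rule for named genes and the alternatives listed next were set before the data were examined. They were relative log expression size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, a stricter filter of 1 CPM in 5 libraries, the replicate number as a block, the compared groups alone, the summed expression of 8 genes of the W chromosome as a covariate, leaving out chromosomes Z and W, and leaving out each library in turn. For the lists they were an estimated correlation, fry, the block and the covariate. Leaving out replicates 3, 4 and 5 of Ogye at 5 weeks, testing all entries of the table and, for the lists, leaving out replicate 1 of Cornish at 5 weeks were added after the data were seen.

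Each contrast was repeated on 100 splits of its libraries into groups of the same sizes, the real split included, drawn with a fixed seed. For breed at 5 weeks and age in Ogye all 21 splits that keep the 3 libraries together, and all 21 without them, were also counted. In each group of 5 libraries the highest or lowest value was compared with Dixon's critical value of 0.71, for library measures and for genes of the first and last part of the naming rule. The tests were tested on simulated data of the size of the comparison at 10 weeks, with 100 of 10697 genes changed at each of 2 sizes. Changed genes were drawn from those with a mean of at least 1 CPM, and the spread was estimated over all 20 libraries. The quasi-likelihood test called 53% of the 2-fold and 91% of the 4-fold changes with 2.7% false calls, DESeq2 62% and 95% with 15.1%, and limma-voom 47% and 89% with 3.5%. A raised list was found, and 0 random lists were called. Genes were simulated independently of each other, so this could not show false list calls that come from correlation between genes. No library and no column of the table was left out.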

Results

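Liver RNA of 2 chicken breeds was sequenced to ask how their hepatic transcriptomes differ while their body weights diverge. Ogye is a Korean native breed and Cornish is a meat breed, and each was sampled at 5 and at 10 weeks of age. The 4 groups held 5 libraries each, 20 libraries in all, and replicates are named by their number within a group. Libraries held between 14865637 and 31848768 counts. Between 9625549 and 21106844 of these fell on entries named by a gene symbol. The lowest total belonged to replicate 5 of Cornish at 10 weeks. Levels are given as CPM, counts scaled to 1e+06 counts of named genes, as mean ± SD with n = 5. Changes are given as log2 fold change ± standard error. The labels do not say whether libraries of a group came from different birds, so p-values measure the spread between libraries. This spread was estimated over the 4 groups together and not from the compared groups alone. After genes with too few counts were removed, 10697 named genes were tested.

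Albumin (ALB), the main secreted liver protein, took between 4.09% and 19.1% of the counts on named genes. Both extremes were Ogye libraries at 10 weeks, replicate 2 and replicate 4. The first principal component held 43.7% of the variance and set replicates 3, 4 and 5 of Ogye at 5 weeks, with scores of 85.6, 89.4 and 86.5, apart from the other 17 libraries, which scored between -36.3 and 5.7. In these 3 libraries expression relative to the median library fell with gene length, with Spearman correlations across genes of -0.62, -0.63 and -0.62. Their genes in the shortest bin, with a median span of 3.34 kb, lay 0.80, 1.03 and 0.93 above the median library on the log2 scale. Genes in the longest bin, with a median span of 91.4 kb, lay at -0.78, -0.77 and -0.78. The interferon-induced gene IFI6 stood at 6720, 887 and 5890 CPM in them, against 36.8 and 49.1 CPM in replicates 1 and 2 of their group. The count of each comparison is therefore also given without these 3 libraries, an alternative added after the data were seen, which tested 10957 genes.

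**Figure D1:**
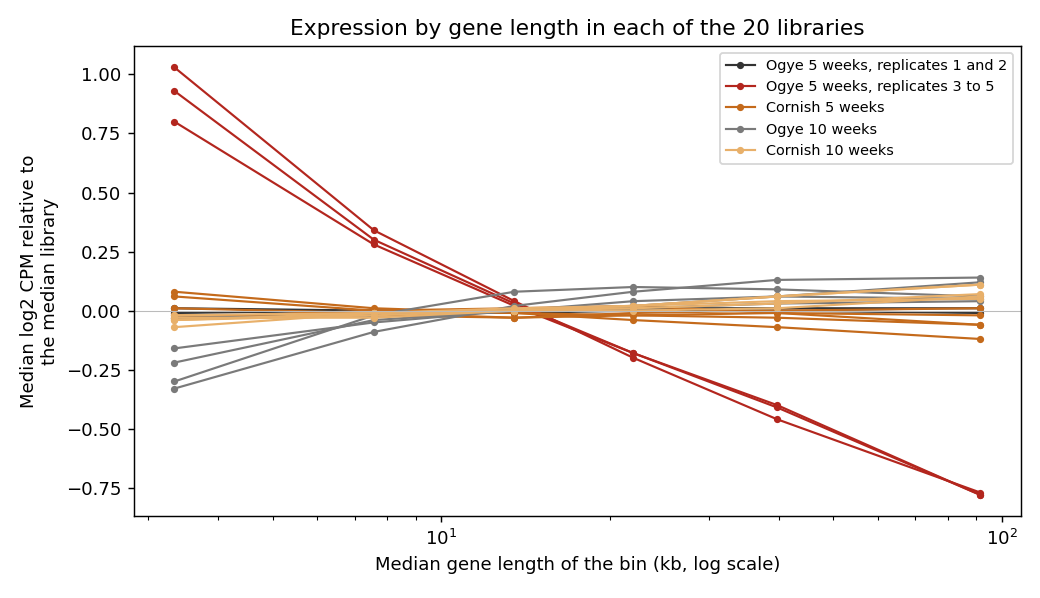
Median expression of genes in 6 bins of gene length, as log2 CPM relative to the median library (vertical axis) against the median gene span of the bin in kb (horizontal axis, log scale), with a line for each of the 20 libraries. Replicates 3, 4 and 5 of Ogye at 5 weeks run from between 0.80 and 1.03 in the shortest bin to between -0.78 and -0.77 in the longest.

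At 5 weeks, the comparison of Cornish with Ogye asked which liver genes differ between the breeds at the younger age. SULT1B1, a cytosolic sulfotransferase on chromosome 4 (51305859 to 51308157), was at 57.3 ± 14.1 CPM in Ogye and 4.41 ± 1.04 CPM in Cornish, a log2 fold change of -3.70 ± 0.39 (adjusted p = 4.5e-05). URAH, which hydrolyses an intermediate of uric acid breakdown and lies on chromosome 11 (18508353 to 18509994), went from 10.8 ± 5.28 CPM in Ogye to 0.64 ± 0.317 CPM in Cornish (log2 fold change -4.06 ± 0.39, adjusted p = 2.2e-05). The yolk lipoprotein APOV1 was lower in Cornish by the widest margin among named genes, with a log2 fold change of -5.82 ± 1.09 (adjusted p = 0.0063). The metallothioneins MT4 and MT3, which bind zinc and copper, and DIO3, which inactivates thyroid hormone, were lower by -3.92 ± 0.80, -3.58 ± 1 and -3.59 ± 0.99. In the other direction stood CDHR5, a cadherin-related protein, with 0.388 ± 0.479 CPM in Ogye and 11.8 ± 4.32 CPM in Cornish (log2 fold change 5.02 ± 0.90, adjusted p = 0.0055). SLC22A2, STMN3, ACHE, SCUBE2 and THSD7B were also higher in Cornish, by 3.49 to 4.84 on the log2 scale. The libraries of the 2 breeds did not overlap for any of these 12 genes. THSD7B and the metallothioneins varied widely inside a group, and reads of MT3 and MT4, neighbouring paralogues on chromosome 11, cannot be told apart from the count table.

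Single genes of growth and lipid metabolism were called at 5 weeks, but the growth hormone and IGF list (adjusted p = 0.91) and the fatty acid synthesis list (adjusted p = 0.14) were not. The growth hormone receptor GHR was higher in Cornish (229 ± 38.1 CPM in Ogye, 358 ± 30.9 CPM in Cornish, log2 fold change 0.65 ± 0.16, adjusted p = 0.013), and so was the insulin receptor substrate IRS1 (1.06 ± 0.23, adjusted p = 0.0085). IGF1, the circulating growth factor made in liver under growth hormone, stood at 22.6 ± 6.14 and 23.0 ± 4.49 CPM, a difference within the spread between replicates (log2 fold change 0.03 ± 0.28, adjusted p = 0.95). IGF2 (adjusted p = 0.69), IGFBP2 (adjusted p = 0.26), FASN (adjusted p = 0.071), CYP7A1 (adjusted p = 0.088) and THRSP (adjusted p = 0.89) did not pass the test either, with log2 fold changes of -0.18 ± 0.31, -0.67 ± 0.44, 1.15 ± 0.44, 1.39 ± 0.57 and -0.12 ± 0.59. GPAM, which begins glycerolipid synthesis, and PLIN2, a coat protein of lipid droplets, were higher in Cornish by 3.06 ± 0.62 and 2.75 ± 0.51 (adjusted p = 0.0072 and 0.0063). CPT1A, which admits fatty acids to mitochondria, was lower by -1.61 ± 0.42 (adjusted p = 0.017). PLIN2 and CPT1A belong to the fatty acid oxidation list, which was not called at 5 weeks either. Without the 3 libraries GHR lost its call (log2 fold change 0.41, adjusted p = 0.38, range over its alternatives 9.5e-05 to 0.38), as did IRS1, GPAM and PLIN2 at 1.06, 2.24 and 2.60 with 2 Ogye libraries left, while CPT1A kept it.

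Of 30 gene lists, 6 stood apart from the other genes at 5 weeks, all lower in Cornish. All 64 tested ribosomal proteins were lower, 64 also when adjusted over the list alone, with a median log2 fold change of -0.98, and RPL37A, RPL37, RPS24 and RPL36 led them (adjusted p = 6.3e-27 for the list, camera). Of 58 nuclear genes of oxidative phosphorylation 47 were lower, 53 when adjusted over the list alone (adjusted p = 1.1e-15), among them COX7C at -1.43 ± 0.27. Of 30 acute phase and coagulation genes 7 were lower, 7 when adjusted over the list alone, such as AMBP, ORM1, HPX and F7 (adjusted p = 0.00032). Of 26 macrophage markers 10 were lower, also 10 when adjusted over the list alone, such as NCF1C, C1QB, VSIG4 and C1QA (adjusted p = 0.0027). Of 29 interferon response genes 8 were lower, 10 when adjusted over the list alone, and STAT2, IFI35, DHX58 and IRF7 led them (adjusted p = 0.0053). Of 33 genes of xenobiotic metabolism 8 were lower and 2 higher, the same numbers when adjusted over the list alone (adjusted p = 0.019). None of the 6 lists passed with the correlation between genes taken from the data, where each had an adjusted p = 0.72 with an estimated correlation. In Ogye at 5 weeks 3 of 5 libraries carried the length trend, and IFI6 was highest in replicates 3 and 5. Without the 3 libraries 0 genes were called in the ribosomal, oxidative phosphorylation, acute phase, macrophage and interferon lists, although the ribosomal, acute phase and macrophage lists stayed called lower, with medians of -0.19, -0.25 and -0.24. In that fit the interferon list turned upwards (adjusted p = 6.6e-05, range over its alternatives 2.5e-05 to 0.72). The xenobiotic list lost its call there (adjusted p = 0.053) and without replicate 1 of Cornish at 5 weeks (adjusted p = 0.072, range over its alternatives 0.0005 to 0.72). Leaving out 1 library gave 11 to 56 lower genes of oxidative phosphorylation and 3 to 10 of xenobiotic metabolism, fewest without replicate 4 of Ogye at 5 weeks. It gave 4 to 11 acute phase, 6 to 12 macrophage and 0 to 17 interferon genes, with 0 of the interferon genes without replicate 3 or 5 of Ogye or 3 of Cornish at 5 weeks.

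In total 2042 genes were called at 5 weeks by the quasi-likelihood test of edgeR, 722 higher and 1320 lower in Cornish, and 663 of them changed by at least 1 on the log2 scale. A fit to the 2 compared groups alone called 56 genes, and one with the W-linked covariate 92. The W-linked sum was 4.33 to 6.78 in Ogye and 6.59 to 7.03 in Cornish at this age, on the log2 CPM scale. The covariate therefore goes partly with breed, and the lower count cannot be read as an effect of sex. Of 21 splits of the libraries that keep the 3 libraries together, 6 gave as many genes as the real one, which is counted among them. The share in each direction depended on the method, with 3013 higher and 2964 lower by limma-voom with quality weights, and 17 higher and 82 lower without the 3 libraries. Libraries of the 2 breeds were fully separated for 6.85% of genes, where chance gives 0.79%. The fit without the 3 libraries called 99 genes, 60 of them among the 2042, while 294 of the 2042 turned sign. URAH, SULT1B1, CDHR5, STMN3, ACHE and CPT1A stayed called there, while 7 other genes did not. Of these, APOV1, DIO3, SLC22A2 and SCUBE2 had log2 fold changes of -4.71, -3.05, 4.46 and 3.86 there, and THSD7B, MT3 and MT4 of 2.71, -2.70 and -2.33. Of 36 named calls at 5 weeks 32 were lost in some alternative. Here and below this tally takes list members only from lists that were called, so other genes described in the text are outside it. URAH had a log2 fold change of -3.13 (adjusted p = 0.00091, range over its alternatives 1.6e-22 to 0.013) and SULT1B1 one of -3.32 (adjusted p = 0.0024, range 1.1e-20 to 0.0024). Leaving out replicate 1, 2, 3, 4 or 5 of Ogye at 5 weeks gave 3945, 3788, 895, 686 or 807 genes, and leaving out replicate 3, 4 or 5 of Cornish at 5 weeks gave 1196, 1244 or 1171.

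At 10 weeks the same comparison asked which liver genes differ between the breeds at the older age. IGF1 was higher in Cornish, at 27.9 ± 2.25 CPM against 9.88 ± 5.01 CPM in Ogye (log2 fold change 1.5 ± 0.29, adjusted p = 0.0057), and IGFBP2, an IGF carrier protein on chromosome 7 (22879236 to 22951723), at 13.2 ± 6.48 CPM against 1.29 ± 0.645 CPM (3.34 ± 0.53, adjusted p = 0.0017). IGF2 was higher by 1.08 ± 0.31 (adjusted p = 0.041) and SOCS2, a feedback inhibitor of growth hormone signalling, by 1.78 ± 0.32 (adjusted p = 0.0038). GHR was lower in Cornish, 625 ± 81.7 CPM against 950 ± 188 CPM in Ogye (log2 fold change -0.60 ± 0.16, adjusted p = 0.024). CYP7A1, the rate-limiting enzyme of bile acid synthesis, was lower as well, 33.4 ± 28.2 CPM against 159 ± 95.9 CPM (log2 fold change -2.25 ± 0.59, adjusted p = 0.024). FASN (adjusted p = 0.59) and THRSP (adjusted p = 0.80), both of fatty acid synthesis, differed by -0.45 ± 0.44 and 0.33 ± 0.59, within the spread between replicates. Libraries did not overlap for IGF1, IGFBP2, SOCS2 and GHR, and they did for IGF2 and CYP7A1. IGF2 lost its call in 9 of 31 alternatives (adjusted p up to 0.091), among them leaving out replicate 1, 3, 4 or 5 of Ogye or 1, 3 or 5 of Cornish at 10 weeks. GHR lost it in 3 (up to 0.07), among them without replicate 1 of either breed at 10 weeks, and CYP7A1 in 4 (up to 0.066), among them without replicate 4 of Ogye or 3 or 4 of Cornish.

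**Figure D2:**
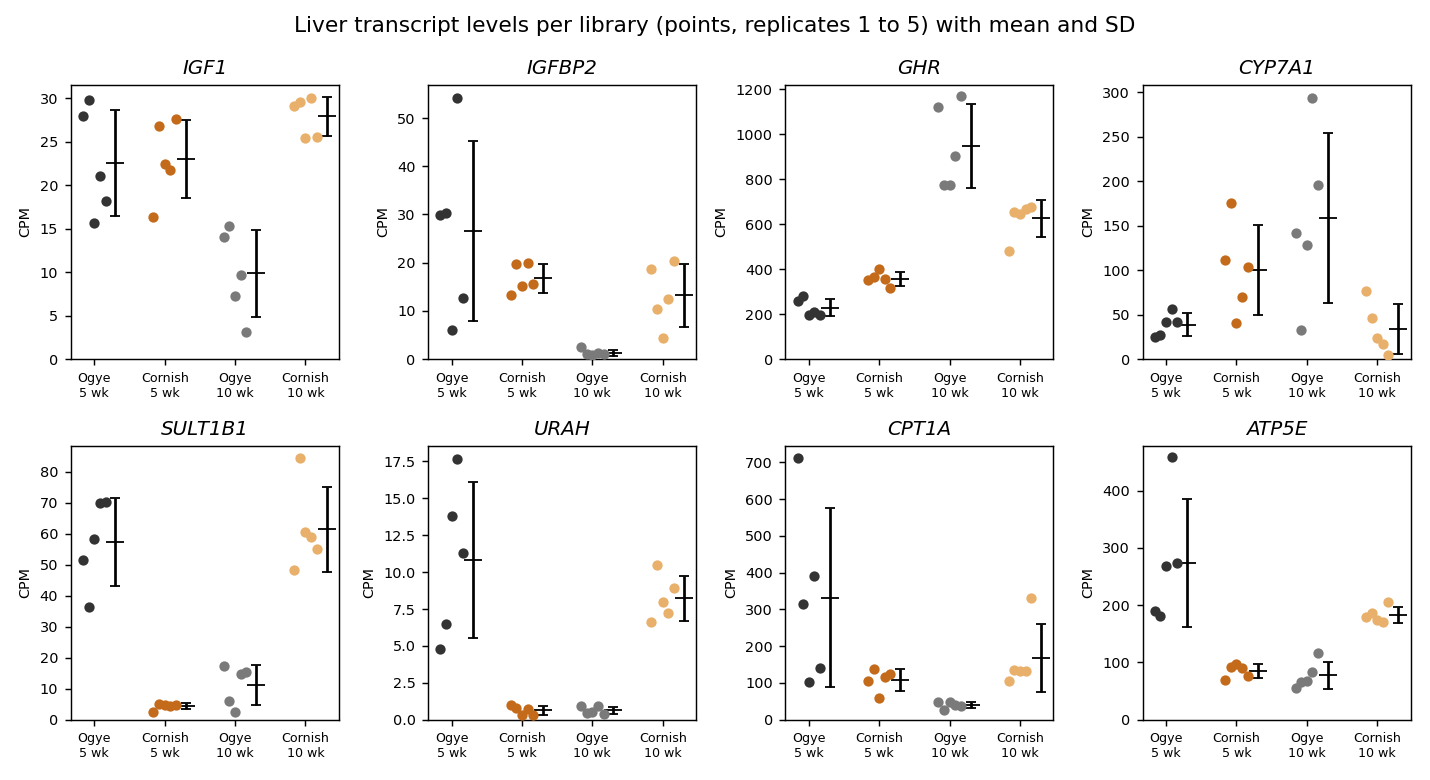
CPM in each library (points, vertical axis from 0) of 8 genes in the 4 groups, replicates 1 to 5 from left to right, with the group mean and SD beside them. IGF1 averaged 9.88 CPM in Ogye at 10 weeks and between 22.6 and 27.9 CPM in the other groups, and SULT1B1 averaged 57.3 and 61.4 CPM in Ogye at 5 weeks and Cornish at 10 weeks against 4.41 and 11.2 CPM in the other groups.

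The widest differences at 10 weeks were those of APOV1 (log2 fold change 5.28 ± 0.92), MYH1B (4.95 ± 1.08), CYP2C18 (4.76 ± 0.93), CA4 (3.83 ± 0.74) and URAH (3.69 ± 0.41), all higher in Cornish, with adjusted p between 0.00011 and 0.01. Lower in Cornish were genes of antimicrobial defence, namely the beta-defensin AvBD7 (-4.25 ± 0.70), DEFB4A (-3.38 ± 0.73) and the goose-type lysozyme LYG2 (-3.48 ± 0.46), together with TGM3, GPR173 and BDKRB2 at -4.08 ± 0.78, -4.06 ± 0.62 and -3.42 ± 0.71. LYG2 stood at 716 ± 267 CPM in Ogye and 64.3 ± 35.1 CPM in Cornish (adjusted p = 0.0004). Libraries of the breeds did not overlap for these 11 genes. AvBD7 and DEFB4A lie side by side on chromosome 3, and CYP2C18, MYH1B and both defensins belong to families of similar genes whose reads the count table does not tell apart.

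Lists at 10 weeks gave 11 calls, 10 higher in Cornish and heterophil markers lower. Of 33 xenobiotic metabolism genes 11 were higher, 18 when adjusted over the list alone, and 1 was lower either way (adjusted p = 2.9e-10, camera, and adjusted p = 0.29 with an estimated correlation). SULT1B1 led them at 2.46 ± 0.37, with CYP3A4, UGT1A1 and CYP1A1 at 1.86 ± 0.30, 1.87 ± 0.34 and 2.96 ± 0.56. Of 27 genes of fatty acid oxidation and ketogenesis 6 were higher, 14 and 1 lower when adjusted over the list alone (adjusted p = 1e-07, and adjusted p = 0.35 with an estimated correlation), among them CPT1A, PPARGC1A and HADHB. CPT1A stood at 168 CPM in Cornish and 39.9 CPM in Ogye. Of 13 heterophil markers, the avian counterpart of neutrophil genes, 7 were lower, 9 when adjusted over the list alone (adjusted p = 4.8e-07, and adjusted p = 0.29 with an estimated correlation), among them LYG2, LECT2, CATH2 and CATH3. Replicate 1 of Ogye at 10 weeks stood apart on LECT2, CATH2 and CATH3, with LECT2 at 205 CPM against 11.1 to 45.5 CPM in replicates 2 to 5, and leaving out 1 library gave 5 to 8 lower heterophil genes. The growth hormone and IGF list had 6 of 22 genes higher and 2 lower, the same numbers when adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.35 with an estimated correlation). Lipoprotein and yolk genes had 5 of 18 higher, 7 when adjusted over the list alone (adjusted p = 0.00018, and adjusted p = 0.35 with an estimated correlation). Thyroid hormone genes had 2 of 14 higher, TTR among them, and 4 when adjusted over the list alone (adjusted p = 0.0039, and adjusted p = 0.40 with an estimated correlation). Carotenoid and retinoid genes had 2 of 12 higher, SCARB1 and ALDH1A1, and 4 when adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.39 with an estimated correlation). TTR and ALDH1A1 lost their calls in 7 and 6 of 31 alternatives (adjusted p up to 0.088 and 0.10), both without replicate 1 or 3 of Ogye or 2, 4 or 5 of Cornish at 10 weeks. Leaving out 1 library gave 3 to 6 higher genes of the growth hormone and IGF list (3 without replicate 1 or 3 of Ogye or 1 of Cornish at 10 weeks) and 3 to 6 lipoprotein genes (3 without replicate 3 of Ogye or 1 of Cornish).

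Further lists called at 10 weeks moved little per gene. Oxidative phosphorylation had 1 of 58 genes higher, NDUFV1, and 0 when adjusted over the list alone, with a median of 0.33 (adjusted p = 1e-07, and adjusted p = 0.67 with an estimated correlation). NDUFV1 lost its call in 18 of 31 alternatives (adjusted p up to 0.13), among them leaving out any single library of 10 weeks but replicate 5 of Ogye. Ribosomal proteins had 0 of 64 called either way, with a median of 0.18 (adjusted p = 0.00088, and adjusted p = 0.73 with an estimated correlation), and the W-linked covariate ended this call (adjusted p = 0.17, range over its alternatives 6.1e-07 to 0.73). Expression relative to the median library rose with gene length at 10 weeks, with Spearman correlations of 0.12 to 0.39 in Ogye and 0.15 to 0.23 in Cornish, and genes in the shortest bin lay at -0.33 to -0.03 in Ogye and -0.07 to -0.02 in Cornish. Glucose and glycogen genes had 4 of 35 higher and 3 lower, 8 and 4 when adjusted over the list alone, with LDHB higher and PFKFB3, PDHA2 and PGM1 lower in Cornish (adjusted p = 0.017, and adjusted p = 0.50 with an estimated correlation). These calls were lost in 5, 8, 6 and 13 of 31 alternatives (adjusted p up to 0.069, 0.12, 0.074 and 0.10), each of them without replicate 3 of Ogye or replicate 1 or 5 of Cornish at 10 weeks. Without replicate 3 of Ogye or 1 of Cornish the list had 0 genes called. Bile acid genes had 0 of 18 higher and 1 lower, CYP7A1, and 1 and 1 when adjusted over the list alone (adjusted p = 0.04, and adjusted p = 0.50 with an estimated correlation), a list not called without the 3 libraries or with the W-linked covariate. The acute phase list was not called (adjusted p = 0.079), and its genes went both ways. Without replicate 1 of Cornish at 5 weeks 4 of its 30 genes were higher and 7 lower, 5 and 10 when adjusted over the list alone. Lower in Cornish were transferrin TF (-1.62 ± 0.31, adjusted p = 0.0053), ceruloplasmin CP (-2.91 ± 0.58, adjusted p = 0.0062) and EXFABP (-2.81 ± 0.64, adjusted p = 0.012). TF reached 71300 and 60100 CPM in replicates 2 and 3 of Ogye, the pair of libraries in which ALB took 4.09% and 4.86% of counts.

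In total 818 genes were called at 10 weeks, 434 higher and 384 lower in Cornish, and 412 changed by at least 1 on the log2 scale. Libraries of the breeds were separated for 12.3% of genes, where chance gives 0.79%. The 3 Ogye libraries of 5 weeks bear on this contrast through the shared estimate of spread, and without them 1882 genes were called, all 818 among them. Of 39 named calls 12 were lost in some alternative. Leaving out replicate 1, 2 or 3 of Ogye at 10 weeks gave 527, 535 or 460 genes, and replicate 1, 2, 4 or 5 of Cornish at 10 weeks 534, 482, 511 or 532.

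EDN3, a secreted ligand of pigment cell precursors on chromosome 20 (11141887 to 11158648, build GRCg7b), lies at the locus known for the dark pigmentation of fibromelanotic breeds, to which Ogye belongs. In liver it was near the detection limit, with at most 18 counts and 1.12 CPM in any library. It differed by -1.16 ± 0.53 at 5 weeks (adjusted p = 0.12) and 0.57 ± 0.59 at 10 weeks (adjusted p = 0.62), and passed the test at neither age. At 5 weeks EDN3 stood at 0.132 CPM in replicate 4 of Ogye and 0.689 to 1.12 CPM in its other replicates. Cornish libraries of that age held 0.194 to 0.441 CPM. Of 70 annotated genes within 500 kb, 35 were tested. At 5 weeks 9 were called, 7 lower and 2 higher in Cornish, and at 10 weeks 4, 3 higher and 1 lower. The same 9 and 4 were called when adjusted over the list alone. Over all tested genes 19.1% were called at 5 weeks and 7.65% at 10 weeks, and an excess around EDN3 was not tested. ATP5E, a small subunit of mitochondrial ATP synthase at 11228568 to 11229745, was lower in Cornish at 5 weeks (274 CPM in Ogye and 85.2 CPM in Cornish, log2 fold change -1.69 ± 0.23, adjusted p = 0.00092) and higher at 10 weeks (77.4 and 183 CPM, 1.24 ± 0.23, adjusted p = 0.0041), without overlap of libraries at either age. ACOT8 and CTSA were also lower at 5 weeks (-1.03 ± 0.28 and -0.68 ± 0.17, adjusted p = 0.021 and 0.014) and higher at 10 weeks (1.11 ± 0.29 and 0.91 ± 0.17, adjusted p = 0.025 and 0.0044). The span of CTSA holds ZSWIM1, and the count table does not show whether reads of this pair were told apart. GNAS and NPEPL1 were higher at 5 weeks and STX16 lower at 10 weeks. Without the 3 Ogye libraries 2 genes stayed called at 5 weeks, ATP5E and ZNF831. At 5 weeks 14 genes were called without replicate 1 of Ogye at 5 weeks and 5 without its replicate 4 or 5, and at 10 weeks 2 without replicate 1 or 2 of either breed at 10 weeks.

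**Figure D3:**
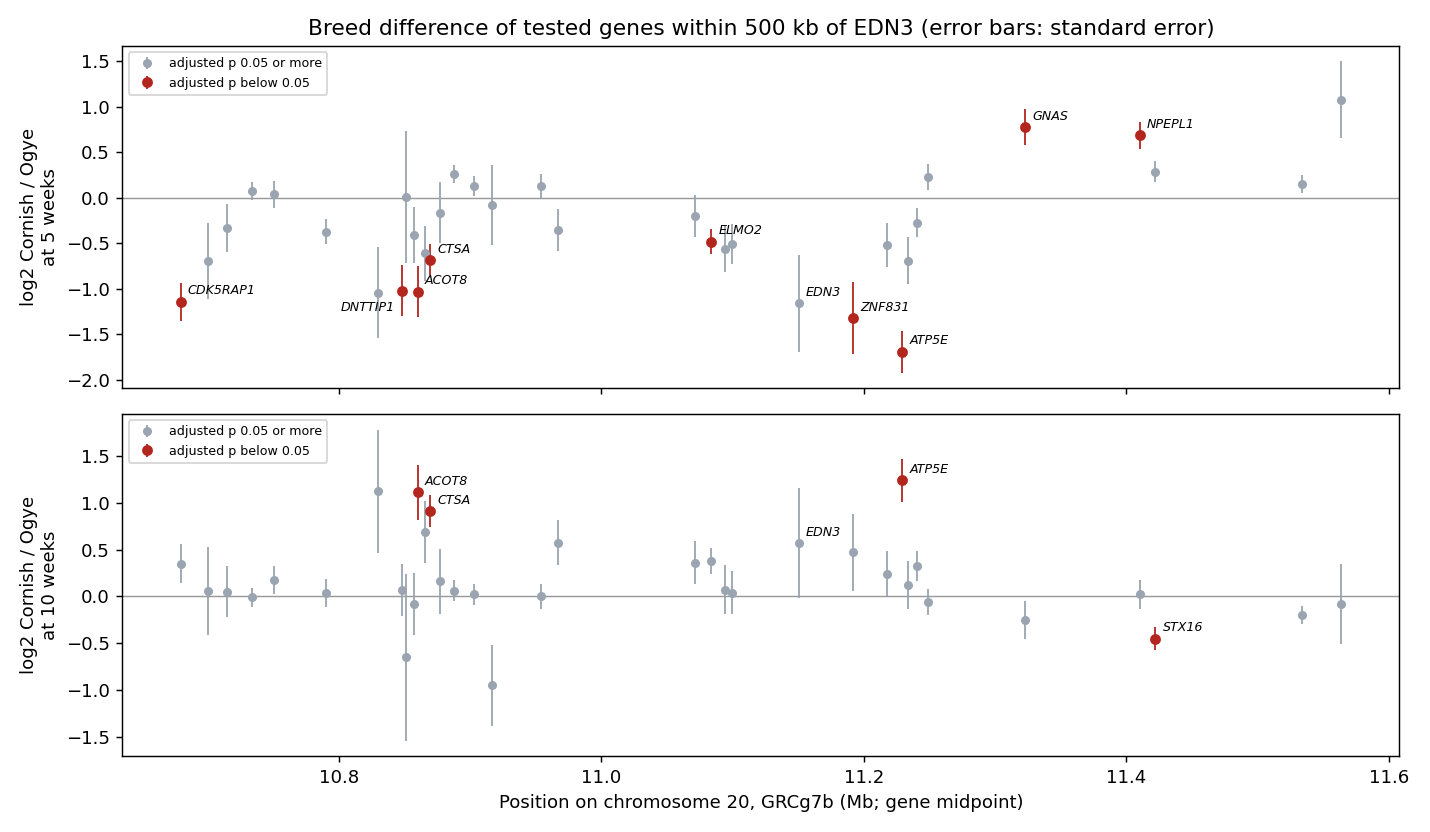
Breed difference as log2 of Cornish over Ogye (vertical axes) for the 35 tested genes within 500 kb of EDN3, at 5 weeks (top) and 10 weeks (bottom), against position on chromosome 20 in Mb. Bars are standard errors, named points in red have an adjusted p below 0.05 over all genes, and ATP5E lies at -1.69 at 5 weeks and 1.24 at 10 weeks.

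Between 5 and 10 weeks in Ogye the growth hormone and IGF list and the fatty acid synthesis list were not called (adjusted p = 0.80 for each), and single genes of them were. GHR rose from 229 ± 38.1 to 950 ± 188 CPM (log2 fold change 2.05 ± 0.16, adjusted p = 4e-07), while IGF1 fell by 1.2 on the log2 scale (adjusted p = 0.0031) and IGFBP2 from 26.6 ± 18.8 to 1.29 ± 0.645 CPM (-4.35 ± 0.54, adjusted p = 4.1e-05). CYP7A1 rose by 2.05 ± 0.58 (adjusted p = 0.0082) and FASN by 1.26 ± 0.44 (adjusted p = 0.026), while IGF2 (adjusted p = 0.18) and THRSP (adjusted p = 0.28) did not pass, at -0.51 ± 0.31 and -0.79 ± 0.59, and EDN3 stood at -1.02 ± 0.57 (adjusted p = 0.15). The neurotrophin receptor NTRK2, the transcription factors RFX6 and BHLHA15, SCUBE2 and TGM3 were among those that rose most, by 4.16 to 5.18. RASAL3 fell from 20.6 ± 5.48 to 0.925 ± 0.272 CPM (-4.44 ± 0.22, adjusted p = 1.8e-10), and URAH, POLD4, PPP1R3G and MUSK fell, with log2 fold changes of -4.08, -3.88, -3.8 and -3.79. Libraries of the ages did not overlap for these 11 genes, the 5 that rose and the 6 that fell, IGFBP2 included. In the fit without the 3 libraries, with 2 Ogye libraries left at 5 weeks, FASN (0.97, adjusted p = 0.32, range over its alternatives 0.0033 to 0.32) and CYP7A1 (2.63, adjusted p = 0.063, range 0.00086 to 0.063) lost their calls and POLD4 stood at -1.71. Counting this fit, FASN lost its call in 7 of 31 alternatives and CYP7A1 in 1.

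Of the lists, 7 were called in Ogye between the ages. Ribosomal proteins fell in 64 of 64 genes, also 64 when adjusted over the list alone (median -1.2, adjusted p = 6.2e-24, camera), and oxidative phosphorylation in 54 of 58, 55 when adjusted over the list alone, with 1 gene higher (adjusted p = 2.9e-16). Interferon response genes fell in 21 of 29, also 21 when adjusted over the list alone (adjusted p = 0.00018), with OASL and IFI6 at -6.04 ± 1.18 and -6.72 ± 1.32. Xenobiotic metabolism fell in 19 of 33 and rose in 4, 20 and 4 when adjusted over the list alone (adjusted p = 0.0052), and in 10 without replicate 4 of Ogye at 5 weeks or 3 at 10 weeks and 12 without its replicate 2 at 10 weeks. Fatty acid oxidation fell in 14 of 27 and rose in 2, the same numbers when adjusted over the list alone (adjusted p = 0.011), with CPT1A at -3.05 ± 0.45 against the lipid droplet protein PLIN2 at 2.62 ± 0.51. Heterophil markers rose in 10 of 13, also 10 when adjusted over the list alone (adjusted p = 0.011), led by LYG2, S100A12, LECT2 and MMP9. Matrix and stellate cell genes rose in 15 of 33 and fell in 5, 16 and 5 when adjusted over the list alone (adjusted p = 0.047), led by PDGFRA, DCN, FBLN5 and COL6A2. Each had an adjusted p = 0.91 with an estimated correlation. With the 3 libraries left out the interferon list was not called (adjusted p = 0.88, range over its alternatives 7e-05 to 0.91). The other 6 lists stayed called there, and ribosomal proteins fell in 29 genes with a median of -0.40. Spearman correlations of expression with gene length were 0.06 and -0.02 in replicates 1 and 2 of Ogye at 5 weeks. In Ogye at 10 weeks they were 0.12 to 0.39, with genes of the shortest bin at -0.33 to -0.03. Whether this length trend contributes to the fall of ribosomal proteins was not tested. The replicate number as a block gave 6 called lists in place of 7.

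Over all genes 4931 changed with age in Ogye, 2273 up and 2658 down, and 2169 by at least 1 on the log2 scale. Libraries of the ages were separated for 19.9% of genes against 0.79% by chance. Leaving out the 3 libraries gave 1531 genes, 1243 of them among the 4931, and 223 of the 4931 turned sign. By limma-voom 3407 went up and 3273 down. Of 44 named calls 10 were lost in some alternative.

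In Cornish livers GHR also rose with age, from 358 ± 30.9 to 625 ± 81.7 CPM (log2 fold change 0.80 ± 0.16, adjusted p = 0.0058), whereas IGF1 (0.28 ± 0.28, adjusted p = 0.58), IGF2 (0.75 ± 0.31, adjusted p = 0.14), IGFBP2 (-0.35 ± 0.44, adjusted p = 0.68), FASN (-0.33 ± 0.44, adjusted p = 0.68), THRSP (-0.34 ± 0.59, adjusted p = 0.77), CYP7A1 (-1.59 ± 0.57, adjusted p = 0.09) and EDN3 (0.71 ± 0.55, adjusted p = 0.45) did not pass the test. APOV1 rose from 0.178 ± 0.127 to 107 ± 74.0 CPM (9.19 ± 1.16, adjusted p = 0.00022), and VWDE, MYH1B, TRPM5, CTSEAL and BDKRB1 by 4.38 to 7.09. SULT1B1 rose by 3.80 ± 0.39 (adjusted p = 2.1e-05). RASAL3 fell from 28.0 ± 2.50 to 1.35 ± 0.278 CPM (-4.36 ± 0.21, adjusted p = 1.2e-10), close to its change in Ogye, and TRIM7.1, PALM2AKAP2, CDHR5, SMOC1 and THSD7B fell, with log2 fold changes of -8.35, -4.93, -4.78, -4.04 and -3.97. Libraries of the ages did not overlap for these 6 rising and 6 falling genes. TRIM7.1 lies on chromosome 16 among related TRIM genes, whose reads the count table does not tell apart.

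Of the lists, 12 were called in Cornish. Acute phase and coagulation genes rose in 13 of 30, 15 when adjusted over the list alone (adjusted p = 1.5e-07, camera, and adjusted p = 0.43 with an estimated correlation), led by PLG, C5, AMBP and F2, and in 5 without replicate 1 of Cornish at 5 weeks or 1 or 3 at 10 weeks and 7 without replicate 3 or 4 at 5 weeks or 4 at 10 weeks. Cell cycle genes fell in 7 of 51, and in 44 when adjusted over the list alone, with a median of -2 (adjusted p = 2e-06, and adjusted p = 0.60 with an estimated correlation), among them CCNB3, TYMS, AURKA and CDC45. Replicate 1 of Cornish at 5 weeks stood apart on these, with AURKA at 20.2 and TYMS at 26.4 CPM against at most 2.01 and 3.67 CPM in replicates 2 to 5. Without it 0 cell cycle genes were called, 0 also when adjusted over the list alone, with a median of -0.30, and the list was still called lower (adjusted p = 0.0026, range over its alternatives 8.7e-07 to 0.60). Leaving out other single libraries gave 0 cell cycle genes without replicate 2 of Cornish at 10 weeks, 1 without its replicate 1, 3 or 4, and up to 20. Xenobiotic metabolism rose in 8 of 33 and fell in 1, 14 and 1 when adjusted over the list alone (adjusted p = 3.1e-06, and adjusted p = 0.55 with an estimated correlation). The interferon list lay lower (adjusted p = 0.00092, and adjusted p = 0.60 with an estimated correlation) with 0 of 29 genes called either way. The same library was highest of its group in MX1, OASL, IFI6 and USP18, with MX1 at 234 CPM against 4.32 to 32.1 CPM, and without it the list had a median of -0.40 in place of -0.87 (adjusted p = 0.048, range over its alternatives 1.6e-06 to 0.60). The list of EDN3 and its neighbours had 3 of 9 genes higher, TUBB1, ATP5E and ZNF831, and 4 higher and 1 lower when adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.43 with an estimated correlation). ZNF831 lost its call in 7 of 31 alternatives (adjusted p up to 0.083). Lipoprotein genes rose in 4 of 18, APOV1, APOH, SCARB1 and APOB, and in 5 when adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.55 with an estimated correlation). Macrophage markers rose in 3 of 26, LY86, HMOX1 and NCF1C, and in 3 when adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.55 with an estimated correlation). Amino acid breakdown rose in 3 of 43, MAT1A, AHCY and PCCA, and in 3 when adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.60 with an estimated correlation). Fatty acid oxidation rose in 2 of 27, ACADS and PDK4, also 2 when adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.60 with an estimated correlation). Bile acid genes rose in 1 of 18, SLCO1B3, also 1 when adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.55 with an estimated correlation). Carotenoid and retinoid genes rose in 3 of 12, SCARB1, ALDH1A2 and DHRS3, and in 4 when adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.55 with an estimated correlation). Endothelial markers lay higher with 0 of 23 called either way (adjusted p = 0.044, and adjusted p = 0.60 with an estimated correlation). Without replicate 1 of Cornish at 5 weeks the amino acid, bile acid, carotenoid and endothelial lists lost their calls, the carotenoid list also without the 3 Ogye libraries, and the bile acid, carotenoid and endothelial lists with the W-linked covariate, while matrix and stellate cell genes were called lower. PDK4, SLCO1B3, SCARB1, APOB, AHCY, PCCA, ALDH1A2 and DHRS3 lost theirs as well.

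Over all genes 787 changed with age in Cornish, 435 up and 352 down, and 333 by at least 1 on the log2 scale, with 16.3% of genes separated against 0.79% by chance. Without the 3 Ogye libraries, which enter this contrast through the shared spread, 2219 were called, all 787 among them, and of 42 named calls 16 were lost in some alternative. Leaving out replicate 1, 3 or 4 of Cornish at 5 weeks gave 409, 473 or 501 genes, and replicate 1, 2, 3 or 4 of Cornish at 10 weeks 442, 379, 459 or 498.

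As labelled, the breed difference changed between the ages for 2500 genes by the test of the interaction. Of these, 1418 had a more positive Cornish effect at 10 weeks and 1082 a more negative one, where limma-voom gave 2755 and 3001. Breed labels exchanged at 1 age would also give such a change, and no test told this apart from a true one. SULT1B1 (6.16 ± 0.53, adjusted p = 1.2e-06), URAH (7.75 ± 0.56, adjusted p = 1.8e-07) and APOV1 (11.1 ± 1.41, adjusted p = 8.3e-05) went from lower to higher in Cornish. CDHR5 (-9.86 ± 1.27, adjusted p = 9.2e-05) and TRIM7.1 (-13.2 ± 2.22, adjusted p = 0.00082) had means in the opposite order, with CDHR5 at 12.2 CPM in Ogye and 0.393 CPM in Cornish at 10 weeks. The fitted interactions of such genes rest on groups with almost no counts and are no bounds. GHR (-1.25 ± 0.22, adjusted p = 0.0011), CYP7A1 (-3.64 ± 0.82, adjusted p = 0.0048), IGF1 (1.48 ± 0.40, adjusted p = 0.014), IGF2 (1.26 ± 0.44, adjusted p = 0.045) and IGFBP2 (4 ± 0.69, adjusted p = 0.00089) also changed their breed difference with age. In contrast, FASN (-1.59 ± 0.62, adjusted p = 0.067), EDN3 (1.73 ± 0.79, adjusted p = 0.11) and THRSP (0.45 ± 0.83, adjusted p = 0.71) did not pass. The fit without the 3 libraries gave 1491 genes, 1030 of them among the 2500, and IGF2 was not called at 1.25 ± 0.53 (adjusted p = 0.12, range over its alternatives 0.0088 to 0.34), a call lost in 15 of 30 alternatives, 13 of them leaving out 1 library. Of 51 named calls 16 were lost in some alternative.

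Of the lists, 9 were called for the interaction. Ribosomal proteins had 60 of 64 genes with a positive interaction, 64 when adjusted over the list alone (adjusted p = 1.2e-21, camera), and oxidative phosphorylation 49 of 58 and 54 (adjusted p = 3.7e-17). Positive were also xenobiotic metabolism 18 of 33 and 21, with 2 negative (adjusted p = 1.2e-07), and fatty acid oxidation 15 of 27 and 17, with 2 negative (adjusted p = 0.0001), and 9 without replicate 3 of Ogye or 2 of Cornish at 10 weeks. Lipoprotein genes had 5 of 18 (adjusted p = 0.013), the same 5 when adjusted over the list alone, and glucose and glycogen genes 11 of 35 with 3 negative, the same either way (adjusted p = 0.015). Macrophage markers had 9 of 26 and 10 (adjusted p = 0.008) and carotenoid and retinoid genes 4 of 12 and 5 (adjusted p = 0.038). Matrix and stellate cell genes had 7 of 33 negative and 1 positive, 8 and 2 when adjusted over the list alone, led by POSTN, PDGFRA and LOX (adjusted p = 0.023). Each had an adjusted p = 0.53 with an estimated correlation, except matrix and stellate cell genes with an adjusted p = 0.57 with an estimated correlation. With the 3 libraries left out, 9 ribosomal and 3 oxidative phosphorylation genes were called. Both lists stayed called there with medians of 0.36 and 0.34, while the glucose and glycogen list did not. At 10 weeks genes of the shortest length bin lay at -0.33 to -0.03 in Ogye and -0.07 to -0.02 in Cornish. A contribution of gene length to these medians was not tested. The carotenoid and retinoid list lost its call without replicate 1 of Cornish at 5 weeks (adjusted p = 0.086, camera).

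Across the 10697 genes, breed effects at the ages were opposed, with Pearson's r = -0.35 and Spearman's rho = -0.36 between the log2 fold changes at 5 and 10 weeks, where genes are not independent replicates. No library enters both contrasts. Breed labels exchanged at 1 age would give opposed effects as well. Among genes called at both ages, 164 were lower in Cornish at 5 weeks and higher at 10 weeks, where independent lists would share 53.6, and 76 went from higher to lower, where 25.9 would. Higher in Cornish at both ages were 3 genes and lower at both 3, against 29.3 and 47.4 for independent lists. With those libraries left out r was -0.46, and 62 genes called at both ages had opposite and 1 the same sign. The age effects in Ogye and Cornish had r = 0.12 and rho = 0.18, with 216 genes called in both changing the same way and 135 the opposite way, and r = -0.08 without the 3 libraries.

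Markers of other cell types that a liver sample can hold were also compared, beside the macrophage, heterophil, endothelial and matrix lists above. Lymphocyte markers were not called in any of the 5 contrasts, with adjusted p between 0.068 and 0.85, nor were erythroid markers, with adjusted p between 0.14 and 0.93, cholangiocyte markers, between 0.079 and 0.98, or markers of pancreas, gut, muscle and fat, between 0.062 and 0.38. Without replicate 1 of Cornish at 5 weeks cholangiocyte markers were called lower with age in Cornish (adjusted p = 0.048, range over its alternatives 0.048 to 0.60). The bile duct marker EPCAM was lower in Cornish at 5 weeks (-1.2 ± 0.22, adjusted p = 0.0063), and the haemoglobin genes HBAD (-1.49 ± 0.30, adjusted p = 0.0075) and HBA1 (-1.28 ± 0.30, adjusted p = 0.011) were lower too. Without the 3 libraries that stand apart none of these 3 genes was called, with log2 fold changes of -0.76, -0.89 and -0.46. Pigment cell genes were not called as a list, with adjusted p between 0.36 and 0.93. At 5 weeks the test pointed down for lymphocyte markers with a median of 0.02 and a mean of 0.01, and for cholangiocyte markers with a mean of 0.05 and a median of -0.09.

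The series is filed as profiling of non-coding RNA. Among tested named genes 2 were annotated as long non-coding RNA and 10330 as protein-coding, so the share called could hardly differ. At 5 weeks 1 of the 2 was called, and at 10 weeks 0 (Fisher's exact test, 2-sided, p = 0.35 and 1, adjusted p = 1 for each over the 5 contrasts), and in the age contrasts 1 in Ogye and 0 in Cornish (p = 1 for each, Fisher's exact test). Genes of the female-specific W chromosome summed to between 6.1 and 7.03 on the log2 CPM scale in 19 libraries and to 4.33 in replicate 3 of Ogye at 5 weeks. HINTW had 0 counts in that library, which allows up to 0.176 CPM, and between 29 and 392 counts in the others. HINTW alone points to female birds in 19 libraries and to a male in that one. Ogye at 5 weeks would then mix the sexes. The summed W-linked genes still held 20.2 CPM in that library, so their sum is no clean measure of sex.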

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

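The tests of gene length, depth, exchanged breed labels in both readings, the effect of the 3 Ogye libraries, differing counting and the splits that keep these libraries together were chosen after the results were seen, while the tests of length and of counting as whole explanations and the other splits of the libraries were set out before their results. Dixon's test was run on 32 groups of library measures and 135 groups of named genes of the first and last part of the naming rule, and no other genes were screened. It picked 2 and 19 of them, where chance picks about 1 in 20.

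The first pattern is that replicates 3, 4 and 5 of Ogye at 5 weeks stand apart. Lower depth is argued against, since the lowest total of the 3 is 21.8 and that of the other 17 libraries 14.9, in units of 1e+06 counts. A gene length bias may contribute, since the difference from replicates 1 and 2 had a Spearman correlation of -0.64 with gene length across genes. A trend with the span of the gene on the chromosome is not the whole difference. The SD across genes was 0.97 before and 0.775 after that trend was subtracted, against at most 0.523 in 30 splits of the other groups. A bias with the length of the transcripts themselves was not tested. What remains open is a difference in RNA quality or preparation, for which the labels give no batch, and a state of these birds such as an interferon response, and neither was tested.

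The second pattern is that breed effects at 5 and 10 weeks point in opposite directions. The 3 libraries do not produce it, since the correlation across genes was -0.46 without them. Of 62 entries at 5 weeks and 107 at 10 weeks with an at least 8-fold breed difference and no overlap, 10 were shared, the genes APOV1 and URAH and 8 assembled transcripts, and 10 of 10 had opposite signs, so breed labels exchanged at 1 age might account for the pattern, as might a true change of the breed difference with age, and no test told these apart. Contrasts between ages decide nothing, with 2396 genes between Cornish at 5 weeks and Ogye at 10 weeks against 2219 within Cornish, but 12 between Ogye at 5 weeks and Cornish at 10 weeks against 1531 within Ogye, without the 3 libraries. Groups are described as labelled throughout, and of 10171 genes 72 separated the 20 libraries when labels were crossed at 1 age and 1 as labelled, where 2000 random splits gave at most 9, a count made after about 20 group patterns had been looked at.

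The third pattern is the set of differences between ages shared by both breeds. Counting that differed between the ages is a candidate explanation for part of them. In 595 pairs, assembled transcripts that repeat a named gene had median log2 ratios to it of 0.13 to 0.28 in libraries of 10 weeks. Those of 5 weeks had 0.01 to 0.02, but pairs were kept by an absolute median under 0.1 at that age. Only the ratios at 10 weeks were free to vary, so the gap between the ages cannot decide by itself. Whether counting accounts for all of the age differences stays open. The test set out beforehand found 1491 genes with a called interaction without the 3 libraries, but a change shared by both breeds leaves no interaction, and exchanged breed labels would give one. RASAL3, 20.6 CPM at 5 weeks and 0.925 CPM at 10 weeks in Ogye, and an entry named by a number alone, with a mean of 345 CPM at 5 weeks and 5.24 CPM at 10 weeks, fell in both breeds alike. Age itself stays open, untested apart from these.

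A chance division of the libraries is argued against for the number of genes called for breed at 10 weeks and for age in either breed. The splits treat the libraries of a group as independent, which the labels do not state. A batch shared by the libraries of a group would pass them too. The real split was the only 1 of 100 as large for breed at 10 weeks, with 818 against at most 7. So it was for age in Ogye, with 4931 against at most 3957, and for age in Cornish, with 787 against at most 2. For the interaction the real 2500 stood against at most 1073, but its splits mixed all 20 libraries over the 4 groups. Such splits break up the breed and age differences as well, so they cannot test the interaction alone, and chance is not excluded for it. For breed at 5 weeks 3 of 100 splits gave as many as the real 2042, with at most 2718 in another split. High counts in other splits at 5 weeks and in Ogye came from splits that keep the 3 libraries together, at most 2718 and 3957, against 17 and 24 where they were parted, which points to a structure of the samples. Of all 21 splits at 5 weeks that keep them together 6 gave as many as the real 2042, and of all 21 splits of the libraries left without them 3 gave as many as the real 99, with at most 456, so chance is not excluded for breed at 5 weeks. For age in Ogye the real split was the only 1 as large of 21 with them together, 4931 against at most 3957. So it was of 21 without them, 1531 against at most 635. This is the lowest share that 21 splits can give. For the number of lists called chance cannot be excluded in any contrast. For breed at 5 weeks 96 of 100 splits gave at least the real 6, with at most 18, for breed at 10 weeks 57 at least 11, with at most 19, for age in Ogye 83 at least 7, with at most 18, for age in Cornish 40 at least 12, with at most 20, and for the interaction 64 at least 9, with at most 21.

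Single libraries far from the others of their group were these. Summed W-linked expression was 4.33 on the log2 CPM scale in replicate 3 of Ogye at 5 weeks, and the scaling factor was 1.371 in replicate 1 of Cornish at 5 weeks. In Ogye at 5 weeks APOV1 was at 34.2 CPM in replicate 4 and DIO3 at 4.83 CPM in replicate 5. In Cornish at 5 weeks CYP2C18 was at 1030 CPM and MUSK at 1.07 CPM in replicate 2 and THSD7B at 23.3 CPM in replicate 5. In Ogye at 10 weeks AvBD7 was at 79.6, DEFB4A at 58.7, TGM3 at 15.3 and IGFBP2 at 2.42 CPM in replicate 1. In its replicate 2 CYP2C18 was at 143, DIO3 at 2.35, IGF2 at 83.2 and MT3 at 93.4 CPM, and in its replicate 5 MYBPC3 was at 3.81 CPM. In Cornish at 10 weeks CYP2C18 was at 2230, GHR at 481 and SCUBE2 at 1.08 CPM in replicate 1, CA4 at 417 CPM in replicate 2 and MT4 at 165 CPM in replicate 3.

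Breed effects that differed between the ages by the test of the interaction numbered 2500. Among named genes the interaction on the log2 scale was 11.1 for APOV1, 9.89 for MYH1B, 9.39 for HS3ST3B1, 7.75 for URAH, 7.32 for NDNF, 7.28 for MYBPC3, 4 for IGFBP2, 1.48 for IGF1 and 1.26 for IGF2. It was -13.2 for TRIM7.1, -9.86 for CDHR5, -6.72 for SCUBE2, -6.35 for CD200L, -6.06 for SLC22A2, -6.01 for GPR173, -3.64 for CYP7A1 and -1.25 for GHR. Outside the named genes, 18737 assembled transcripts held at least 1 read, and the entry named by a number had a mean of 345 CPM at 5 weeks.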

How the results depend on the processing

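Leaving out replicates 3, 4 and 5 of Ogye at 5 weeks, testing all entries of the table and, for the lists, leaving out replicate 1 of Cornish at 5 weeks were chosen after the data were seen, and all other alternatives before. A count was taken as kept within 1.5 times the reported one, and a test on the same side of its threshold. The correlation of the breed effects was taken as kept within 0.037 of the reported one. That is its SD over the fits that leave out 1 library, which are themselves scored. For the counts and correlations that answer a comparison, 191 values were kept under the alternatives chosen before and 65 were not. For single genes and lists 7641 kept a call and its direction or stayed uncalled, 381 lost the call, 157 gained it and 1 with a call in either fit turned sign under these, the heat shock list for the interaction with the W-linked covariate (adjusted p = 0.02). Under the added ones these were 721, 53, 46 and 10. Directions of lists and genes that no fit called are not counted. Where no reason is given, the cause was not tested.

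For the breed effect at 5 weeks, 2042 genes, limma-voom with quality weights called 5977, the compared groups alone 56, the W-linked covariate 92, the fit without the 3 libraries 99, with 2 Ogye libraries left, and all entries 3095, with more entries tested. For the breed effect at 10 weeks, 818 genes, DESeq2 called 1242, limma-voom 2265, the compared groups alone 1474, the fit without the 3 libraries 1882 and all entries 1392. For age in Ogye, 4931 genes, the compared groups alone gave 3073, the fit without the 3 libraries 1531 and all entries 7695. For age in Cornish, 787 genes, DESeq2 gave 1340, limma-voom 2845, the compared groups alone 2330, the fit without the 3 libraries 2219 and all entries 1417. For the interaction, 2500 genes, limma-voom gave 5756, the W-linked covariate 953, the fit without the 3 libraries 1491 and all entries 4036. DESeq2 made 15.1% false calls on simulated data.

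The correlation of the breed effects, -0.35, was -0.18 with limma-voom, -0.28 with no filter, -0.40 with the W-linked covariate, -0.46 without the 3 libraries, -0.41 over all entries and -0.45 over genes called at either age. With an estimated correlation between genes 0 lists were called in each of the 5 contrasts. With the W-linked covariate 18 lists were called for breed at 10 weeks and 16 for the interaction, fry called 2 for age in Cornish, and 17 were called for the interaction without the 3 libraries. Around EDN3, limma-voom called 19 genes at 5 weeks and 7 at 10 weeks, and at 5 weeks the compared groups alone gave 1, the W-linked covariate 2 and the fit without the 3 libraries 2. Among lists called in either fit, the breed effect at 5 weeks turned sign without the 3 libraries for oxidative phosphorylation (adjusted p = 0.91), the interferon list (adjusted p = 6.6e-05) and the heat shock list (adjusted p = 0.027). Among genes called in either fit, the same effect turned sign there for STAT2 (log2 fold change 0.25), IFI35 (log2 fold change 0.41), DHX58 (log2 fold change 0.89) and IRF7 (log2 fold change 0.21). The interaction turned sign there for the interferon and heat shock lists (adjusted p = 0.0088 and 0.046). Without replicate 1 of Cornish at 5 weeks the cell cycle list turned downwards for breed at 5 weeks (adjusted p = 1.9e-05) and was called lower at 10 weeks (0.00044) and with age in Ogye (0.012). Matrix and stellate cell genes and endothelial markers were called higher for breed at 5 weeks, and for the interaction the carotenoid list lost its call and the interferon list gained one.

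Leaving out each library in turn gave between 686 and 3945 genes for breed at 5 weeks (lowest without replicate 4 and highest without replicate 1 of Ogye at 5 weeks), between 460 and 1002 for breed at 10 weeks (without replicates 3 and 5 of Ogye at 10 weeks), between 3949 and 5850 for age in Ogye, between 379 and 1048 for age in Cornish (lowest without replicate 2 of Cornish at 10 weeks) and between 1932 and 3599 for the interaction. The correlation of the breed effects ran from -0.42 to -0.26, and the genes around EDN3 from 5 to 14 at 5 weeks and from 2 to 4 at 10 weeks.

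The replicate number as a block stands for a pairing that the labels do not state. With this block 1910, 723, 4948, 652 and 2461 genes were called in the 5 contrasts, in the order above, with a correlation of -0.34. Of 30 pairs of libraries with the same number 7 correlated above 0.1 after group means were removed and 7 were best matched to their own number, so the numbers were not read as pairs. About 53% of simulated 2-fold changes were called, among genes with a mean of at least 1 CPM and with the spread of all 20 libraries. A gene that was not called can therefore still differ.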

Other observations

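The lists and genes of this part were fixed beforehand and no test was added, but which of them to describe was chosen after the results were seen. The clock list was not called with age in Ogye (adjusted p = 0.36), with 6 of 21 genes higher and 5 lower at 10 weeks, where 46.1% of all genes were called. NPAS2, a partner of the clock protein ARNTL, rose from 1.9 to 11.9 CPM (log2 fold change 2.63 ± 0.33, adjusted p = 4e-05), NFIL3, a repressor with a daily rhythm, by 2.66 ± 0.34 (adjusted p = 4.9e-05), CLOCK by 1.12 ± 0.15 (adjusted p = 5.6e-05) and ARNTL by 1.21 ± 0.22 (adjusted p = 0.00039). Libraries of the ages did not overlap for NPAS2, NFIL3 and CLOCK, and they did for ARNTL. In Cornish BHLHE41 fell by 2.31 on the log2 scale (adjusted p = 0.0057) and PER3 by 1.39 (adjusted p = 0.011), without overlap of the 5 and 5 libraries. The labels give no time of day of sampling.

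The list of protein folding in the endoplasmic reticulum was not called with age in Ogye either (adjusted p = 0.19), with 10 of 28 genes higher and 2 lower, and it was called higher without replicates 3, 4 and 5 of Ogye at 5 weeks (adjusted p = 0.00028, range over its alternatives 0.00028 to 0.91). The chaperone DNAJB9 rose by 1.48 ± 0.22 (adjusted p = 0.00011) and SEL1L, which serves the breakdown of misfolded proteins, by 1.76 ± 0.33 (adjusted p = 0.00043), without overlap of libraries, while CREB3L3 changed by -1.72 ± 0.35 (adjusted p = 0.00095). In fatty acid synthesis, a list not called in any contrast, LPIN2 was higher in Cornish at 10 weeks (2.75 ± 0.55, adjusted p = 0.0062) and ACSS2 lower (-1.44 ± 0.34, adjusted p = 0.015). TRPM1, a cation channel known from pigment cells, was higher in Cornish livers at 5 weeks (3.13 and 23.1 CPM, 2.85 ± 0.63, adjusted p = 0.0096), without overlap of libraries, a call that was lost without the 3 Ogye libraries (log2 fold change 2.11), and at 10 weeks it did not pass the test (-1.54 ± 0.60, adjusted p = 0.12).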
